A study of Homo sapiens with 7 samples.

How the data were processed

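Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on MCF10A cells, an established immortalized but non-tumorigenic human mammary epithelial line. Per the labels, the 7 samples were 3 libraries precipitated with an AIB1 antibody, 3 precipitated with a TEAD4 antibody and 1 input library of cell lysate. AIB1, encoded by NCOA3, is a coactivator that binds nuclear receptors and other transcription factors, and TEAD4 is a DNA-binding factor through which the coactivators YAP and TAZ act. The cells were at passage 10 to 15, and their medium held hydrocortisone, insulin, cholera toxin at 100 ng/ml, EGF at 20 ng/ml and horse serum at 5%, per the labels' protocols.

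The deposited values were interval coordinates (chromosome, start and end, in 3 columns), with 1 combined list per factor and no score, height or replicate column. Per the submitters' processing notes, BWA, SAMtools, MACS2 and bedtools were used with the hg38 (GRCh38) assembly. Their versions, settings and order, and the rule that combined the 3 libraries, were not given in the sources used here. Per the labels' design text, the ChIP libraries were normalized to the input. Read depth per library is unknown from interval lists. The numbers of regions, and the classes with 1 factor but not the other, could not be adjusted for it.

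Intervals of a list that shared at least 1 bp were merged into regions, because the deposited lists repeat them. The AIB1 list held 214 exact duplicates among 2124 intervals and the TEAD4 list 1812 among 14090. Nearly all regions were listed either once or 3 times. In all 580 AIB1 and 3257 TEAD4 regions made of 3 intervals, 2 of the starts equalled the largest start and 2 of the ends equalled the smallest end. Pairwise intersections of peaks from 3 libraries give this pattern, so a region listed 3 times was read as a peak in all 3 libraries and a region listed once as a peak in exactly 2. This reading is an inference from the coordinates. The deposited lists are named as intersections, but no source used here states which peaks were intersected.

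The lists, motifs, tests and gene lists were chosen before the data were examined, with intervals as deposited as the unit. The change of unit to merged regions was made after the data were seen, since a test on repeated intervals counts 1 region several times, and values for deposited intervals are given where a call differs. Also chosen after the data were seen were the split into single-copy and multi-copy regions, the restriction to regions listed 3 or more times, TSSs of all transcripts, repeated draws of the random gene lists, further settings for motifs and lists other than those of the main comparisons, and the comparison of motif content between AIB1 regions without TEAD4 and TEAD4 regions without AIB1. A region was called multi-copy when at least 50% of its 50-bp words occurred more than once in the hg38 sequence, and single-copy otherwise. Copies that differ at a base in every such word count as single-copy, so misassigned reads are not fully excluded there.

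Overlap was counted at a minimum of 1 bp and compared with 100000 random placements of the AIB1 regions, with the same widths and chromosomes and outside assembly gaps of 1 kb or more. Alternatives used 10000 placements, so the smallest p they can give is 0.0001, against 1e-05 for the main test. Distances ran from the region midpoint to the transcription start site (TSS) of the canonical transcript of the nearest of 20007 protein-coding genes in GENCODE release 44, with negative values upstream. A midpoint within the annotated span of a gene but outside canonical exons was called intronic. Introns can therefore include sequence upstream of a canonical TSS. Shares were compared by two-sided Fisher's exact tests and carry Wilson 95% intervals, which cover counting error only. Because the lists hold no score, region width and the number of times a region was listed stood in for strength, with two-sided permutation tests of 100000 resamples for median width.

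The 15 fixed sequence patterns, 2 of them scrambled controls, were searched on both strands in the 200 bp around the midpoint and in a window of equal length 2 kb upstream. The two-sided exact McNemar test compared them, with Benjamini-Hochberg adjustment over all patterns and both lists. Outside the alternatives, McNemar tests in subsets of regions were adjusted together over all subsets and patterns. Comparisons of motif content between groups were adjusted over the 15 patterns of each comparison. The p63 pattern was searched in its full form, and a shorter core also written down for it was not used. Gene lists were tested by the number of members with a region within 50 kb of the TSS, against 10000 random lists of equal size drawn from 19962 protein-coding genes of chromosomes 1 to 22 and X and matched on deciles of the number of TSSs within 100 kb. Drawing within deciles is a permutation of list membership among genes of like density. The random lists do not reproduce neighbouring members, which can share a region. The p-values of lists with such members can therefore be too small. These p-values were one-sided and adjusted over 18 lists and both factors. For regions with both factors, and for AIB1 regions without TEAD4, they were adjusted over the 18 lists alone. The lists were YAP/TAZ-TEAD targets, Hippo pathway components, AP-1 and related factors, EGF family and ERK feedback genes, adhesion and matrix genes, TGF-beta and EMT genes, Wnt pathway genes, NF-kappaB and cytokine genes, glucocorticoid-responsive genes, estrogen receptor targets and luminal genes, basal epithelial genes, cell cycle genes, nuclear receptor coregulators, ribosomal protein genes, and hepatocyte, neuronal, blood, and fibroblast and endothelial genes.

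Named genes followed a fixed rule. It took the nearest genes of the 10 widest regions with both factors, with AIB1 alone and with TEAD4 alone, the 4 members of each gene list closest to a region of each factor (all members for the YAP/TAZ-TEAD list), and the 5 genes with the most regions within 50 kb. Those first in rank were named, with the exceptions given here. The widest single-copy regions and the genes with the most single-copy regions were added after the data were seen, and 1 of the 10 with both factors, like some members of the gene lists, is not reported here. Genes outside the rule are marked as chosen after their values were seen.

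Alternatives covered the overlap that counts as shared, the wider 50% of each list, placement matched on distance to the TSS, other TSS distances and annotations, whole regions, a longer TEAD pattern, downstream and GC-matched backgrounds, and other list distances and tests. The overlap, motif, gene list and permutation tests and the count of repeated words were tested on simulated data, and the random placement by location and the stratified odds ratios were not. In the overlap test, 1 of 40 random sets gave p under 0.05 and 279 overlaps were counted where 278 had been planted. For the motif test, 19.0% of windows were recovered where 19% of 2000 had been given the motif. Of 200 random gene lists, 8 gave p under 0.05, and 18 of 18 planted members were counted. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9. Reads, signal tracks and per-library peaks were not used here.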

Results

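The series mapped where AIB1 and TEAD4 sit on the genome of MCF10A mammary epithelial cells, with 3 ChIP libraries for each factor and 1 shared input library. Each factor was represented by 1 combined list of intervals on hg38. Nothing in the labels says that the 3 libraries of a factor came from separate cultures, and no value per library could be compared. All p-values below are therefore over regions or genes, not over replicates.

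Many more regions were listed for TEAD4 than for AIB1. The AIB1 list comprised 944 merged regions covering 308.1 kb, and the TEAD4 list 7504 regions covering 2204.76 kb. The median region was 268 bp wide for AIB1 (range 10 to 2555 bp) and 264 bp for TEAD4 (range 3 to 2568 bp). Of the AIB1 regions, 585 (62.0%) were listed 3 or more times and 359 once, against 3274 (43.6%) and 4230 for TEAD4. These numbers, widths and shares were not tested between the lists, and the read depth behind each list is unknown.

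Most AIB1 regions coincided with TEAD4. AIB1 lay with TEAD4 in an intron of AXL, a receptor tyrosine kinase gene, and downstream of CCN1, which encodes a matricellular protein and is a well-known YAP target. Both factors also met upstream of DUSP1, a phosphatase gene that restrains MAP kinases, near KRT6A and KRT17, which encode basal keratins, and near PER1, a circadian clock gene that responds to glucocorticoids. Most TEAD4 regions had no AIB1, which follows from the much shorter AIB1 list.

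In all, 588 of 944 AIB1 regions overlapped a TEAD4 region (62.3%, Wilson 95% interval 59.2 to 65.3%). Random placement gave a mean of 1.70 overlaps and at most 10, so the observed number was 346-fold higher (one-sided permutation p = 1e-05 over random placements, the smallest they can give). For intervals as deposited the share was 63.9% (1358 of 2124). Conversely, 589 of 7504 TEAD4 regions overlapped AIB1 (7.85%). Among single-copy regions 384 of 708 AIB1 regions overlapped a single-copy TEAD4 region (54.2%, 50.6 to 57.9%), 358-fold over random. Both lists were normalized to the same input, so part of the overlap can come from the shared control, which cannot be simulated from interval lists. Random placement also takes no account of open chromatin.

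**Figure D1:**
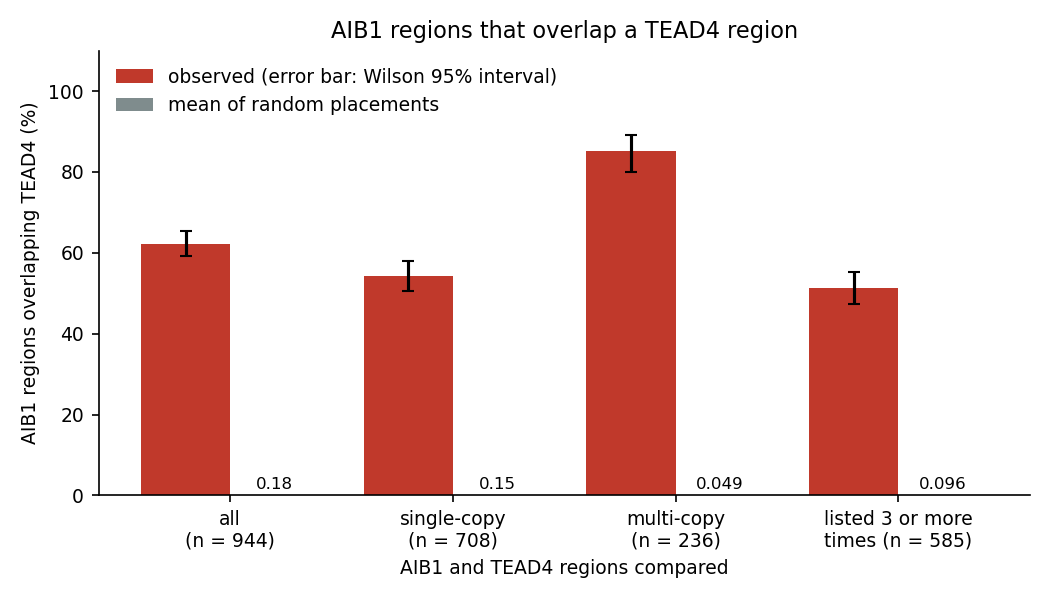
Share of AIB1 regions that overlapped a TEAD4 region (%), with Wilson 95% intervals, for all, single-copy, multi-copy and repeatedly listed regions, beside the mean of random placements (numbers at the axis). The observed shares ran from 51.3% to 85.2%, and each random mean was below 1%.

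At CCN1, TEAD4 had 6 regions within 50 kb of the TSS, and the only AIB1 region there, at chromosome 1, 85607092 to 85607579, was intergenic, 26575 bp downstream of the TSS, and overlapped TEAD4. The AXL region with both factors lay in an intron at chromosome 19, 41226025 to 41226330. At DUSP1 the shared AIB1 region was intergenic at chromosome 5, 172772351 to 172772698, its midpoint at -1330 bp. Both loci drawn in the map of CCN1 and DUSP1 were chosen after their values were seen.

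**Figure D2:**
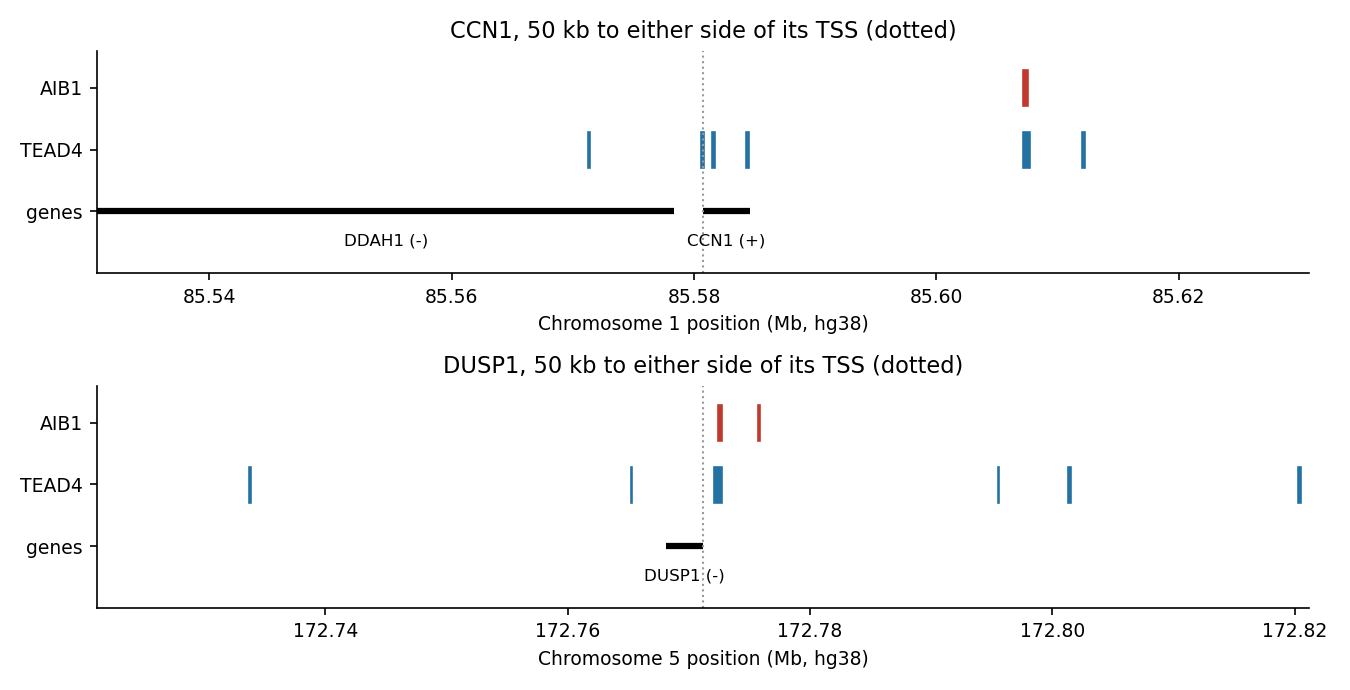
Maps of AIB1 regions (red), TEAD4 regions (blue) and protein-coding genes (black, strand in brackets) within 50 kb of the CCN1 and DUSP1 TSSs, by position in Mb on hg38. The CCN1 promoter carried TEAD4 without AIB1, and AIB1 met TEAD4 26575 bp downstream, while at DUSP1 both met close to the TSS.

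Repeated sequence took a large part of the AIB1 list. The largest group lay on the short arm of chromosome 21. Other large groups were in arrays of near-identical genes, namely the TAF11L genes on chromosome 5 and the USP17L deubiquitinase genes on chromosome 4. Groups of like size on chromosome X and elsewhere on chromosome 4 held no protein-coding gene. Of the AIB1 regions, 236 (25%, 22.3 to 27.9%) were multi-copy, against 636 TEAD4 regions (8.48%, 7.87 to 9.13%; Fisher p = 6.52e-44). On chromosome 21, between 8204979 and 8471305, all 41 multi-copy AIB1 regions overlapped TEAD4, as did all 16 in the TAF11L array between 17517695 and 17599331. Overlap was partial in other groups, with 12 of 15 in the USP17L array and 12 of 16 on chromosome X. A chromosome 19 group starting at 36284335 had 5 of 9. Multi-copy AIB1 regions overlapped TEAD4 more often than single-copy ones (86.0%, 203 of 236, against 54.4%, 385 of 708; Fisher p = 9.41e-20). Reads from such sequence cannot be assigned to 1 copy, so genes in these arrays are uncertain. Copies of 1 sequence can draw the same reads, yet the tests here and below count each copy as a separate region. Their p-values and intervals can therefore be too small and too narrow for multi-copy regions.

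TEAD4 regions that overlapped AIB1 were wider and more often listed repeatedly. Those with AIB1 had a median width of 386 bp against 259 bp without it (permutation p = 1e-05, the smallest the resamples can give). They were listed 3 or more times in 71.8% of cases against 41.2% (Fisher p = 5.5e-47). In single-copy sequence the medians were 353 and 259 bp. AIB1 regions with TEAD4 were wider than those without it (300.5 against 248 bp, permutation p = 1e-05), by less in single-copy sequence (272 against 249 bp, permutation p = 0.00129). Width and repeated listing are stand-ins, as the lists hold no peak height. A wider region is more likely to share 1 bp with another, so part of the width differences can follow from the overlap rule. Regions listed 3 or more times were also wider, so these stand-ins are not separate measures.

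The factors differed in where they sat relative to genes. TEAD4 was found at promoters, including those of LATS2, a Hippo pathway kinase gene, CCN2, a matricellular YAP target, MYC, a growth-promoting transcription factor gene, and TEAD4 itself. AIB1 was seldom there, although regions lay close to the TSSs of MT2A, a metallothionein gene, COL7A1, which encodes anchoring fibril collagen, and KRT17. It was mostly intergenic or in introns.

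Within 1 kb of a protein-coding TSS lay 35 AIB1 regions (3.71%, 2.68 to 5.11%) and 921 TEAD4 regions (12.3%, 11.6 to 13.0%; Fisher p = 2.21e-18). Random placement gave 1.38% and 1.46% (two-sided permutation p = 0.002 each, the smallest that 1000 placements can give). In single-copy sequence the shares were 2.54% and 12.7% (Fisher p = 1.92e-20). Over 50 kb from any such TSS lay 519 of 944 AIB1 and 38.9% of TEAD4 regions (Fisher p = 6.97e-21). Random placement gave 61.2% and 59.9%, so both factors lay that far from a TSS less often than random positions (two-sided permutation p = 0.002 each, the smallest the placements can give). Introns held 32.7% and 41.3%, exons 1.91% and 2.04%, and intergenic sequence 61.7% and 44.4%. Single-copy TEAD4 regions with AIB1 lay within 1 kb of a TSS less often than those without it (2.56%, 10 of 390, against 13.4%, 865 of 6478; Fisher p = 6.05e-13). With TSSs of all annotated genes the AIB1 share was 14.7% and the TEAD4 share 18.6% (Fisher p = 0.00356), a smaller difference.

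**Figure D3:**
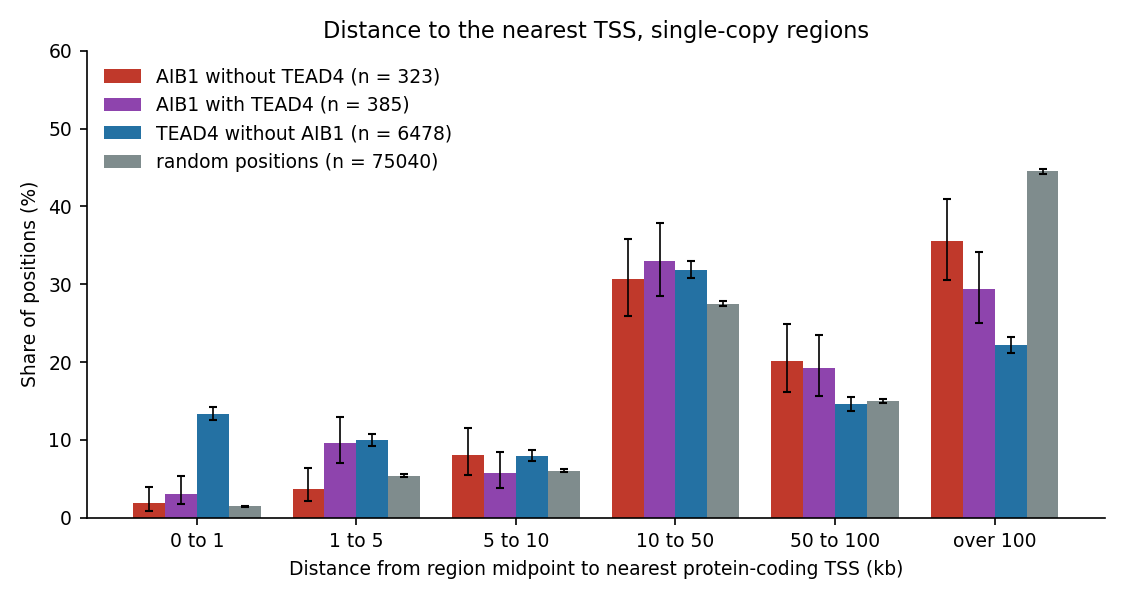
Share of single-copy regions (%) by distance from the midpoint to the nearest protein-coding TSS (kb), with Wilson 95% intervals, for AIB1 without TEAD4, AIB1 with TEAD4, TEAD4 without AIB1 and random positions. Only TEAD4 without AIB1 exceeded 10% within 1 kb (13.4%).

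TEAD4 regions were rich in the sequence TEAD proteins bind. The TEAD core GGAATG stood in 55.3% of TEAD4 region centres, against 10.9% of the flanks. Sites of AP-1, the FOS and JUN family, and of RUNX, SP/KLF, NF-kappaB and C/EBP factors were also more frequent in TEAD4 centres. AIB1 centres held AP-1, RUNX, TEAD and C/EBP sites and glucocorticoid response elements (GREs), the palindrome bound by the glucocorticoid receptor and its relatives. No centre held the estrogen response element searched for, a strict pattern that was almost absent from flanks too.

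In TEAD4 regions the TEAD core was in the centre alone in 3699 and in the flank alone in 366, a difference whose p was too small to be represented. AP-1 sites were in 23.1% of TEAD4 centres against 3.54% of flanks (exact McNemar, adjusted p = 4.22e-281), and RUNX sites in 18.9% against 13.7% (6.52e-17). SP/KLF sites were in 3.28% of TEAD4 centres against 0.893% of flanks (exact McNemar, adjusted p = 1.42e-25), NF-kappaB sites in 4.49% against 2.40% (1.11e-11) and C/EBP sites in 4.97% against 2.88% (2.49e-10), and ETS, E2F, CTCF, E-box and p63 patterns also passed. In AIB1 regions the TEAD core was in 22.2% of centres against 10.7% of flanks (exact McNemar, adjusted p = 6.36e-11), AP-1 in 28.3% against 2.54% (1.15e-56), and RUNX in 23.5% against 12.9% (7.71e-09). C/EBP sites were in 8.05% of AIB1 centres against 2.97% (2.24e-06). GREs were in 7.31% of AIB1 centres against 0.424% of flanks (2.53e-16), and in 0.573% of TEAD4 centres against 0.400% (0.252). The estrogen response element, searched only as a full palindrome, was in 0 of 944 AIB1 centres, with a Wilson upper bound of 0.405%. It was in 0.106% of AIB1 flanks, so the pattern is too rare for its absence from centres to show a depletion. The scrambled TEAD control was lower in centres than in flanks of AIB1 (4.56% against 7.52%) and TEAD4 regions (7.37% against 9.42%).

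AIB1 regions without TEAD4 had no excess of the TEAD core. In the 323 single-copy ones it was in 11.8% of centres and 12.7% of flanks (exact McNemar p = 0.813), against 39% and 10.1% in the 385 with TEAD4. The share of centres with the core differed between these groups (Fisher, adjusted p = 1.04e-15). Grouping by TEAD4 peaks would itself tend to produce this difference. The centres without TEAD4 held AP-1 sites in 41.8% (flanks 4.64%, exact McNemar, adjusted p = 1.03e-26) and GREs in 12.4% (flanks 0.619%, 40 regions, adjusted p = 4.47e-10). Both were also raised in the single-copy centres with TEAD4, AP-1 sites at 31.9% (flanks 2.34%, exact McNemar, adjusted p = 1.66e-27) and GREs at 6.49% (flanks 0.519%, 1.8e-05). The shares of centres with and without TEAD4 differed for each (Fisher, adjusted p = 0.0432 for both). AREG, which encodes the EGF receptor ligand amphiregulin, had the GRE GAACAGACTGTAC at chromosome 4, 74431313 to 74431325, in an intergenic AIB1 region without TEAD4. FKBP5, a glucocorticoid-induced co-chaperone gene, had GAACACAATGTCC at chromosome 6, 35728114 to 35728126. The site lay in an intron of the annotated FKBP5 span but upstream of its canonical TSS. The nearest TSS to that region was that of ARMC12. MT2A had GTACACTGTGTCC upstream of its TSS at chromosome 16, 56608319 to 56608331.

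**Figure D4:**
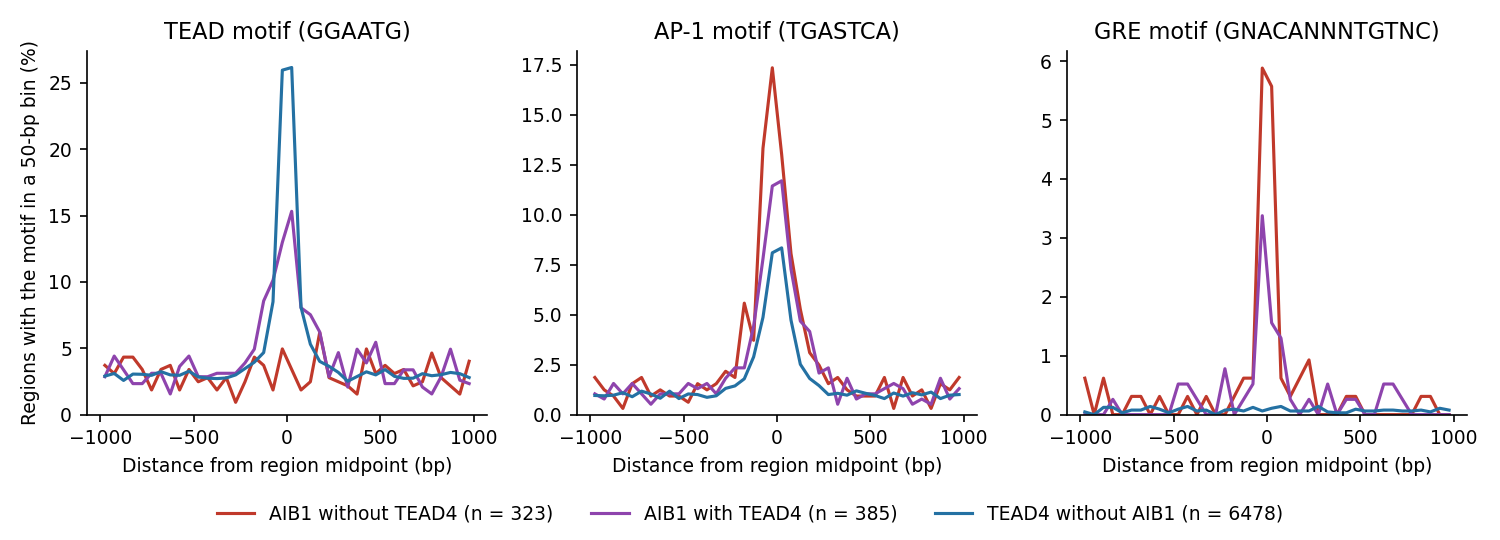
Share of single-copy regions (%) with a TEAD, AP-1 or GRE motif in each 50-bp bin, by distance from the region midpoint (bp), for AIB1 without TEAD4, AIB1 with TEAD4 and TEAD4 without AIB1. AIB1 without TEAD4 shows no TEAD peak but central AP-1 and GRE peaks.

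Whether AP-1 sites differed in the TEAD4 regions that AIB1 shares depended on the unit and on repeats. Over all merged regions they were in 21.6% of TEAD4 centres with AIB1 and 23.3% without it (Fisher, adjusted p = 0.771). For intervals as deposited, the unit first planned, the share was lower with AIB1 (20.9% against 24.4%, Fisher, adjusted p = 0.00929). That unit counts repeated regions more than once. In single-copy regions it was higher with AIB1 (31.0% against 23.9%, Fisher, adjusted p = 0.00949), and it was 30.4% against 26.9% over whole regions (adjusted p = 0.124). Part of the single-copy rise can come from location. AP-1 sites were in 6.51% of single-copy TEAD4 regions within 1 kb of a TSS and 26.9% of the others. Of regions with AIB1, 2.56% lay that close to a TSS, against 13.4% without it. In multi-copy regions the AP-1 share was lower with AIB1 (3.02%, 6 of 199, against 13.7%, 60 of 437; Fisher, adjusted p = 7.7e-05), a contrast added after the data were seen. That p counts each copy of a sequence as a separate region. In the centres the TEAD core was less frequent with AIB1 (35.5% against 57.0%, Fisher, adjusted p = 1.39e-22, and 46.7% against 58.3% in single-copy regions, 6.49e-05). Only 200 bp at the midpoint were searched, and TEAD4 regions with AIB1 were wider (single-copy median 353 against 259 bp). Sites elsewhere in them were not counted, so part of this difference can come from width. The scrambled TEAD control was also lower with AIB1 over all regions (4.41% against 7.62%, Fisher, adjusted p = 0.0151), and did not pass in single-copy regions (6.15% against 7.76%, 0.61). GREs were more frequent with AIB1 (2.72% against 0.390%, Fisher, adjusted p = 4.56e-07).

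TEAD4 lay near most known YAP/TAZ-TEAD target genes. Its regions stood at the promoters of LATS2, CCN2, CCN1, AMOTL2, an angiomotin family gene of the Hippo pathway, ANKRD1, an ankyrin repeat gene induced by YAP, and PTPN14, a phosphatase gene that binds YAP. Adhesion genes were also near TEAD4, including ITGB4, ITGA5 and ITGB1, which encode integrins, and THBS1, which encodes thrombospondin. The genes of the pathway itself, TEAD4, TEAD1 and YAP1, had TEAD4 regions at their TSSs.

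Of 22 YAP/TAZ-TEAD targets, 19 had a TEAD4 region within 50 kb, against 5.60 in matched random lists (permutation of list membership, adjusted p = 0.00072, from the smallest p the lists can give). The LATS2 region was centred in the 5' UTR at chromosome 13, 21061377 to 21061736, and the CCN2 region was intergenic at chromosome 6, 131951290 to 131951658, at -102 bp. The others were CCN1, AMOTL2, ANKRD1, PTPN14, AXL, ARHGEF17, ASAP1, GADD45A, FJX1, CCDC80, DOCK5, CRIM1, MYOF, NUAK2, TGFB2, F3 and NT5E, and none of these 19 nearest regions overlapped AIB1. Hippo components numbered 19 of 29 (expected 8.08, permutation, adjusted p = 0.00072) and adhesion and matrix genes 23 of 27 (7.94, 0.00072).

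Further lists near TEAD4 were AP-1 factors with 12 of 17 (expected 5.92, permutation, adjusted p = 0.0072), such as MAFF, JDP2 and ATF3, and basal epithelial genes with 14 of 20 (7.24, 0.009), such as PKP3 and CDH3, which encode junction proteins. The basal members included the neighbours KRT14, KRT16 and KRT17, and KRT5 and KRT6A. The cytokine and EGF family lists below also hold neighbours, such as CXCL2 and CXCL3, and EREG and AREG. Such members are not independent. NF-kappaB and cytokine genes had 14 of 22 (7.10, 0.009), including CSF2, NFKB2 and NFKB1. EGF family genes had 13 of 23 (6.38, 0.0108), including SPRY2, DUSP6 and ERBB2, but only 5 with regions listed 3 or more times (permutation, adjusted p = 0.409). Wnt genes had 14 of 24 (6.39, 0.00514), including LRP6 and FZD7, a call lost within 10 kb (3, permutation, adjusted p = 0.739) and within 100 kb (15, 0.0538). Glucocorticoid-responsive genes had 10 of 17 (5.31, permutation, adjusted p = 0.0462). This call passed in 10 of 20 other random draws (0.0429 to 0.0534), in 20 of 20 for single-copy regions (0.0312 to 0.0402), and not within 10 kb (0.113), within 100 kb (0.174) or by Fisher's test (0.0599).

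Lists that did not pass near TEAD4 were TGF-beta and EMT genes (8 of 21, permutation, adjusted p = 0.287), estrogen receptor targets and luminal genes (9 of 20, 0.166), cell cycle genes (9 of 25, 0.498) and ribosomal protein genes (15 of 31, 0.149). Among coregulators 8 of 22 were near TEAD4 (0.498), among them NCOA3, the AIB1 gene, with a region at -179 bp. Genes of other cell types did not pass either, with 4 of 24 hepatocyte genes (permutation, adjusted p = 1), 6 of 23 neuronal genes (0.866), 8 of 22 blood genes (0.81) and 8 of 20 fibroblast and endothelial genes (0.277).

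AIB1 lay near glucocorticoid-responsive and basal epithelial genes. The glucocorticoid-responsive genes were MT2A, DUSP1, PER1, KLF9, a Kruppel-like factor gene, ANGPTL4, a lipoprotein lipase inhibitor gene, and FKBP5. The basal genes were KRT17, COL7A1, S100A2, a calcium-binding protein gene, KRT6A, KRT5, KRT16 and KRT14. FKBP5, KRT5, KRT16 and KRT14 lay outside the naming rule and were chosen after their values were seen. Adhesion genes near AIB1 included ITGB4, ITGA3, ITGB6 and ITGB1.

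Of 17 glucocorticoid-responsive genes, 6 had an AIB1 region within 50 kb (expected 0.636, permutation, adjusted p = 0.00072), and of 20 basal genes 7 did (0.722, 0.00072). The 7 basal genes had 6 distinct regions at 4 loci, as KRT14, KRT16 and KRT17 shared 1 region and KRT5 and KRT6A shared 2, so these members are not independent. Adhesion genes had 5 of 27 (0.856, permutation, adjusted p = 0.0048), and 0 within 10 kb. YAP/TAZ-TEAD targets had 3 of 22, namely AXL, CCN1 and AMOTL2 (expected 0.608, permutation, adjusted p = 0.0633), which did not pass, and passed within 100 kb (5, adjusted p = 0.0184) and in single-copy regions (3, 0.0414).

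Other lists near AIB1 did not pass. AP-1 factors (JUNB, FOSB and FOSL1) had 3 of 17 (permutation, adjusted p = 0.067), EGF family genes (DUSP1, EREG and AREG) 3 of 23 (0.067), and TGF-beta genes (such as TGFBR2 and SMAD7) 3 of 21 (0.0629). NF-kappaB and cytokine genes (NFKBIA, CCL20 and LIF) had 3 of 22 (0.0839), and Hippo components (TEAD3, WWC1 and AMOTL2) 3 of 29 (0.117). Each of the first 3 passed within 100 kb, with adjusted p of 0.0172, 0.0024 and 0.0189. In single-copy regions AP-1 factors (adjusted p 0.0414) and TGF-beta genes (0.0432) passed, in 20 of 20 other draws each, while NF-kappaB genes (0.0477) passed in 2 of 20 and EGF family genes (0.0529) in 10 of 20. The Wnt list had 1 of 24 (DKK1, 0.667). Luminal, cell cycle, coregulator and hepatocyte genes had 0 of 20, 25, 22 and 24, and ribosomal, neuronal, blood, and fibroblast and endothelial genes had 1 each of 31, 23, 22 and 20.

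**Figure D5:**
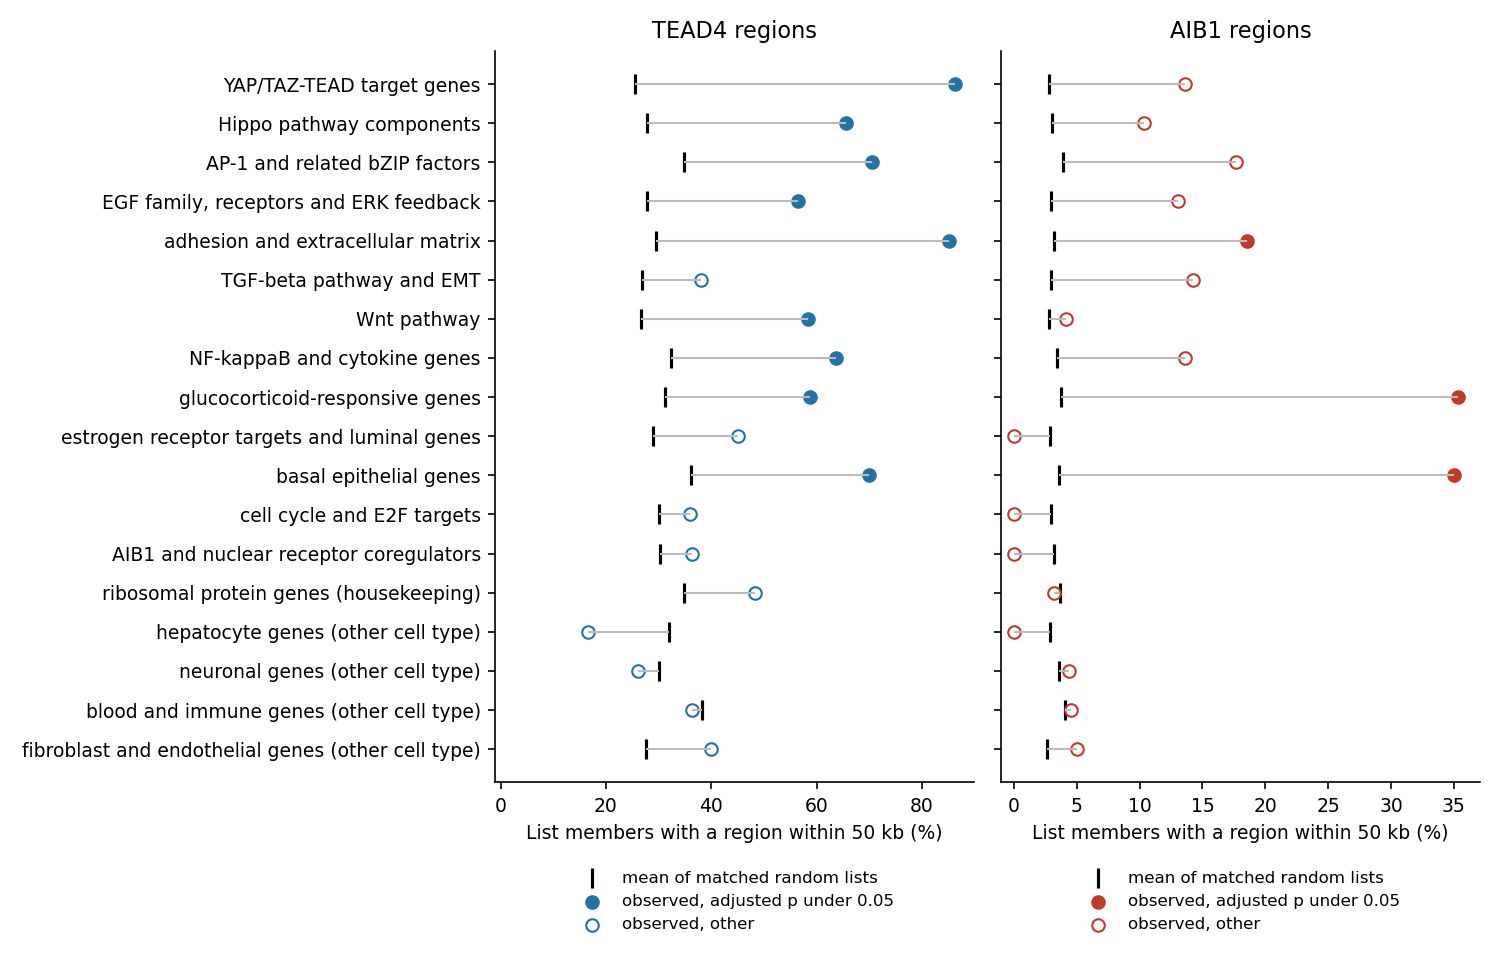
Share of each gene list (%) with a TEAD4 region (left) or an AIB1 region (right) within 50 kb of the TSS, beside the mean of matched random lists; filled points had an adjusted p under 0.05. YAP/TAZ-TEAD targets reached 86.4% for TEAD4, and glucocorticoid-responsive genes 35.3% for AIB1; the filled TEAD4 point for glucocorticoid-responsive genes passed in 10 of 20 other random draws.

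The widest regions with both factors were mostly multi-copy and far from their nearest genes. These were NUPR2 (-255 kb), TPTE (-2128 kb for the widest) and PLS3 (171 kb). In single-copy sequence they lay in an intron of SH3TC2 (chromosome 5, 148965569 to 148966701), near CCL20, a chemokine gene, near KLF9 and near MT2A. The widest AIB1 regions without TEAD4 were nearest to CD7 (19.7 kb), MCF2L2 (57.5 kb), MYC (-67.3 kb) and CYP1B1 (-0.968 kb), a cytochrome P450 gene. TEAD4 regions without AIB1 were widest in introns of CLPTM1L, which was multi-copy, and of LAMA5, a laminin gene, and near MIEF2 and IRF1. Single-copy TEAD4 regions were most numerous within 50 kb of EPHA2, LAMA5 and RPS21, with 9 each, and single-copy AIB1 regions near ID1, with 4. Windows of neighbouring genes can hold the same regions.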

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

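The restriction to single-copy regions, the differences between the factors and all tests in this part were chosen only after the result was seen, except those of element spacing, region strength and GC content. AIB1 regions without TEAD4 and TEAD4 regions without AIB1 differed in motif content, measured as the share of centres minus the share of flanks and tested by permuting the factor over regions. The TEAD core differed by -48.2 percentage points (-0.929 for AIB1, 47.3 for TEAD4). A difference in this core follows largely from grouping the regions by TEAD4 peaks, so it is no separate finding. AP-1 sites differed by 17.0 points (37.2 against 20.2), C/EBP sites by 7.56 (9.60 against 2.04) and GREs by 11.8 (11.8 against -0.0154). These 4 had an adjusted p of 3.75e-05 over 15 patterns, from the smallest p the permutations can give. RUNX sites differed by 12 points (17.6 against 5.67, permutation, adjusted p = 0.00033). Location was not matched in these comparisons. Within 1 kb of a TSS lay 1.86% of the AIB1 regions and 13.4% of the TEAD4 regions compared.

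AIB1 regions overlapped TEAD4 far more than random placement. Repeat copies with identical 50-bp words as the whole cause were argued against, since 54.2% of single-copy AIB1 regions overlapped single-copy TEAD4 regions. Non-specific capture of open promoters was argued against, since 2.56% of the shared single-copy TEAD4 regions lay within 1 kb of a TSS, against 13.4% of the others. Within multi-copy sequence, shared reads may make the overlap, as the TEAD core exceeded flank by 1.97 points there (95% interval -3.45 to 7.39), against 28.8 in single-copy regions. The interval counts each copy as a separate region. Accessible enhancers captured by both antibodies and the shared input stay open, and no biological explanation was tested.

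AIB1 regions without TEAD4 held GREs and AP-1 sites and no TEAD excess. TEAD4 binding at its core that the peak caller missed was argued against as a main source. The TEAD core exceeded flank by -0.929 points (95% interval -5.88 to 4.33), against 42.6 in TEAD4 regions listed once. Binding without the core was not excluded, since only 46.7% of single-copy TEAD4 regions with AIB1 held the core in the 200 bp searched. TEAD4 sites too weak to be listed could not be examined. Base composition was argued against, since the same element with spacings of 2 or 4 bp rose by at most 0.929 points, against 11.8 at 3 bp. As a hypothesis, a receptor that binds the GRE may recruit AIB1 there, since 37 of 41 GREs (90.2%, Wilson 77.5 to 96.1%) lay in the inner 100 bp, against 53.2% if evenly spread (one-sided binomial p = 3.95e-07); that even share replaced a lower value of 50% after the test had been run, with the same outcome. The receptor stays open, as the medium held hydrocortisone and other steroid receptors bind the same element.

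AIB1 was rarer at TEAD4 regions within 1 kb of a TSS, with an odds ratio of 0.171 (95% interval 0.0908 to 0.321) in single-copy regions. Differences in region width and listing were argued against, since the odds ratio within classes of both was 0.175 (0.0925 to 0.329). The lists hold no peak height, so weaker TEAD4 binding at promoters was not excluded. GC content was argued against, since the odds ratio within GC bins was 0.133 (0.0676 to 0.260). No biological explanation was tested, and differences in depth or antibody between the factors stay open.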

How the results depend on the processing

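Single-copy regions, regions listed 3 or more times, deposited intervals outside the overlap result, TSSs of all transcripts, every setting of motifs and gene lists beyond the TEAD, shared AP-1 and YAP/TAZ-TEAD results, and repeated draws were tests chosen only after the result was seen. No paired analysis was possible because each factor has 1 combined interval list with no values per replicate, and leaving out a replicate was not possible for the same reason. Of 68 settings over 12 results of the comparisons, 53 kept direction and side of the threshold, 4 newly passed it, 3 reversed and 8 moved. Of 246 settings over 44 other results, 210 kept both, 7 lost the call, 12 newly passed and 17 reversed. The AIB1 overlap stayed between 51.3% and 72.2%.

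Numbers moved by construction, to 2124 AIB1 and 14090 TEAD4 intervals as deposited and to 585 and 3274 regions listed 3 or more times. Median widths became 259.5 bp for AIB1 in single-copy regions, 252 bp for TEAD4 as deposited, and 329 and 321 bp for regions listed 3 or more times. The TEAD core in AIB1 regions reversed to -1.69 points without TEAD4 (exact McNemar, adjusted p = 0.842). AP-1 sites in shared regions, -1.69 points over all regions, became -3.51 as deposited (Fisher's exact test, adjusted p = 0.00929), 3.45 over whole regions (0.124) and 7.13 in single-copy regions (0.00949), so this result depends on the unit and on repeats. Multi-copy shared regions, with AP-1 sites in 3.02%, account for the change of sign on leaving repeats out, and the cause was not tested for the other settings. YAP/TAZ-TEAD targets near AIB1 passed with 5 members within 100 kb (0.0184), 3 in single-copy regions (0.0414) and 3 in regions listed 3 or more times (0.0292); the cause was not tested.

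The other reversals passed no threshold, except that adhesion genes near AIB1 lost their call with 0 members within 10 kb. GREs in TEAD4 regions became -0.0267 points in the wider 50%, 0 without AIB1 and -0.0916 in regions listed 3 or more times. Near TEAD4, member counts crossed expectation within 10 kb for TGF-beta (2), ribosomal (3) and neuronal genes (3), and for blood genes within 100 kb (13) and by Fisher's test (8). Near AIB1 they did so within 10 kb for Hippo, neuronal and blood genes (0 each), within 100 kb for luminal (2), neuronal (1) and blood genes (1), in single-copy regions for ribosomal genes (1) and in regions listed 3 or more times for blood genes (0). The cause was not tested.

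Over 20 other draws of random lists, run for all and for single-copy regions of each factor, 3 calls depended on the draw. Lists near regions with both factors, or near AIB1 regions without TEAD4, were not redrawn. TEAD4 near glucocorticoid-responsive genes passed in 10 (adjusted p 0.0429 to 0.0534), and single-copy AIB1 near EGF family genes in 10 (0.045 to 0.0559) and near NF-kappaB genes in 2 (0.049 to 0.058). Depth per library is unknown and limits which weaker regions were listed.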

Other observations

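The split of TEAD4 regions by promoter, the counts per chromosome, the list of AIB1 regions with GREs and the gene lists near single-copy AIB1 regions without TEAD4 were tests chosen only after the result was seen. TEAD4 promoter regions carried other sequences than distal ones. In the 875 single-copy regions within 1 kb of a TSS, such as those at MIEF2 and KIF20A, SP/KLF sites were in 13.7% of centres against 1.84% of the 5993 others (Fisher, adjusted p = 5.42e-48). ETS sites were in 3.66% against 0.334% (6.93e-16) and E2F sites in 3.66% against 0.617% (1.49e-11). AP-1 sites were rarer at promoters (6.51% against 26.9%, 9.64e-48), as was the TEAD core (46.4% against 59.3%, 2.33e-12). The scrambled controls were rarer at promoters too, that of TEAD with 5.26% against 8.03% (0.00489) and that of AP-1 with 2.06% against 3.39% (0.0457). Part of the lower shares at promoters is therefore not particular to the motifs. Neither control bears on the higher shares of SP/KLF, ETS and E2F sites. Promoter and other regions were not compared at equal GC content, so whether those rises are particular to the motifs was not tested.

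Several single-copy AIB1 regions with a GRE and without TEAD4 lay at genes outside the rule, named after their values were seen. One was in an intron of ZBTB16, a glucocorticoid-induced zinc finger gene, at chromosome 11, 114160067 to 114160349, and another in an intron of FKBP5 at chromosome 6, 35601911 to 35602155. A pair lay upstream of SCNN1B, an epithelial sodium channel gene, at -43.8 and -45.7 kb. Single-copy AIB1 regions without TEAD4 were near 4 of 17 glucocorticoid-responsive genes (expected 0.224, permutation, adjusted p = 0.0018), 3 of 23 EGF family genes (0.290, 0.0198) and 3 of 27 adhesion genes (0.335, 0.0264). Basal genes did not pass there (2 of 20, adjusted p 0.106), nor did the other lists. Regions with both factors, here with multi-copy ones included, were near 6 of 20 basal genes (0.500, permutation, adjusted p = 0.0018; 4 distinct regions), 4 of 17 glucocorticoid-responsive genes (0.443, 0.0108), 3 of 22 YAP/TAZ-TEAD targets (0.380, 0.0366) and 3 of 17 AP-1 factors (0.474, 0.0468), and the other lists did not pass. The difference between regions with and without TEAD4 was not tested for any list, and the region sets are unlike in their repeats. Per Mb, chromosome 20 had the most single-copy AIB1 regions (0.657) and chromosome 19 the most TEAD4 regions (5.41). Per 100 genes, chromosome 19 had the fewest TEAD4 regions of the autosomes (21.4) and chromosome 20 the most (55). These counts were not adjusted for the number of copies of each chromosome in the cells, which interval lists do not show.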
